A study of Arabidopsis thaliana with 16 samples.

How the data were processed

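The counts are raw read counts per gene as deposited. According to the submitters' processing notes, reads were checked with FastQC 0.11.2, trimmed with Trimmomatic 0.38, aligned to TAIR10 with HISAT2 2.1 and counted with featureCounts 1.6.2, and edgeR 3.34.1 was used for their own tests. RNA with an integrity number above 7 went into stranded mRNA libraries. The annotation, strand setting and read layout are not given in the sources used here. The table has 33297 lines, of which 33296 carry a gene name, 33011 matched a locus of the TAIR10.1 reference and 7100 had no count in any library. Every column belonged to a sample, and the line without a name was left out of the tests.

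Genes were tested with edgeR 4.0.16 under R 4.3.3, by its quasi-likelihood F-test, two-sided, in 1 fit of all 16 libraries with a coefficient per group, TMM scaling and 8 residual degrees of freedom. The expression filter asked for 10 counts and a total of 15 and left 20505 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison. The comparisons were 28 °C minus 22 °C in each genotype, each line minus Col-0 and pSUC2-BRL3 minus brl3-2 at each temperature, and the differences between temperature responses. Principal components used log2 CPM with a prior count of 2.

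The 21 gene lists were written before the data were examined: brassinosteroid receptors, biosynthesis, and signalling with catabolism, PIF4 pathway, auxin response, gibberellin, heat shock, cold-regulated, expansins with xyloglucan enzymes, xylem, phloem, photosynthesis, root, shoot apex with stomatal lineage, cell cycle, flavonoids, salicylic acid, jasmonate, abscisic acid, osmoprotectants and the clock. A list with at least 3 tested members was tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the 21 lists of a comparison. Named genes follow a rule written before the data were examined. BRL3 comes first. Then come the genes with a symbol, a mean of at least 5 CPM in the higher group and both replicates of one group above both of the other, 8 rises and 8 falls in Col-0 and 5 and 5 elsewhere. Interactions drop the replicate condition. From a described list come up to 4 members, and genes with only a locus code are counted but not named. For up to 3 counts in a group folds are bounds or ratios with 95% counting intervals.

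Alternatives written before the data were examined were DESeq2 1.42.0, its size factors, no low-count filter, a replicate block and leaving out each library in turn. Recovery is for 200 genes changed in simulated counts and may differ where more are called. Figures were drawn with matplotlib 3.10.9.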

Results

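Messenger RNA was sequenced from hypocotyls, the embryonic stems, of 6-day-old Arabidopsis seedlings grown throughout at 22 °C or 28 °C under long days. Hypocotyls elongate at the warmer temperature, the growth response called thermomorphogenesis. Of the 4 genotypes, Col-0 was the wild type and brl3-2 a T-DNA insertion mutant of BRL3, a brassinosteroid receptor kinase of the BRI1 family that is active mainly in vascular tissue. The complementation line pSUC2:BRL3;brl3-2, called pSUC2-BRL3 from here on, carried a BRL3-GFP transgene under the SUC2 promoter, active in phloem companion cells, in the brl3-2 background. BRL3ox expressed BRL3-GFP from the strong, general 35S promoter. Each of the 8 combinations had 2 libraries, 16 in all. Total counts per library ran from 19014140 to 22791633 at 22 °C and from 23022123 to 26564829 at 28 °C, and 20505 genes were tested. The labels call the replicates biological without describing how they were grown or harvested, so p-values measure the spread between these samples. Every group had n = 2, single changes are log2 values, and expression is given as mean ± SD CPM, counts scaled to library size.

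Temperature dominated the libraries: the first principal component held 53.7% of the variance and separated 22 °C from 28 °C. The second held 15.1% and set replicate 2 of BRL3ox at 22 °C, at -103, apart from the other 15 libraries. Between the BRL3ox replicates at 22 °C 4523 genes lay at least 2-fold apart, and between those of pSUC2-BRL3 at 28 °C 1576, against 623 to 1158 in the other 6 groups. Every pair of replicates differed by more than sampling noise, with a chi-square per gene of 12.6 to 123. Replicate 2 of BRL3ox at 22 °C and replicate 1 of pSUC2-BRL3 at 28 °C are called the 2 doubted libraries from here on. Which library of pSUC2-BRL3 at 28 °C is odd is not settled: replicate 1 was chosen for its clock genes, but replicate 2 lay at 43.1 on the first component, where the other libraries at 28 °C ran from 56.5 to 84.7. In brackets after a lost list call stands the adjusted p without that library, whose partner is then assumed to vary like the other groups. List calls were tested against all other genes, list counts are out of the members tested, medians are log2 changes, the number over the list alone counts members passing when adjusted within the list, and the list leave-one-outs were added after the list tests had been seen. Counts on nuclear protein-coding genes, without the 2 libraries, or with replicate 2 of pSUC2-BRL3 left out instead (the other pair), come from alternatives chosen after seeing the data.

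**Figure D1:**
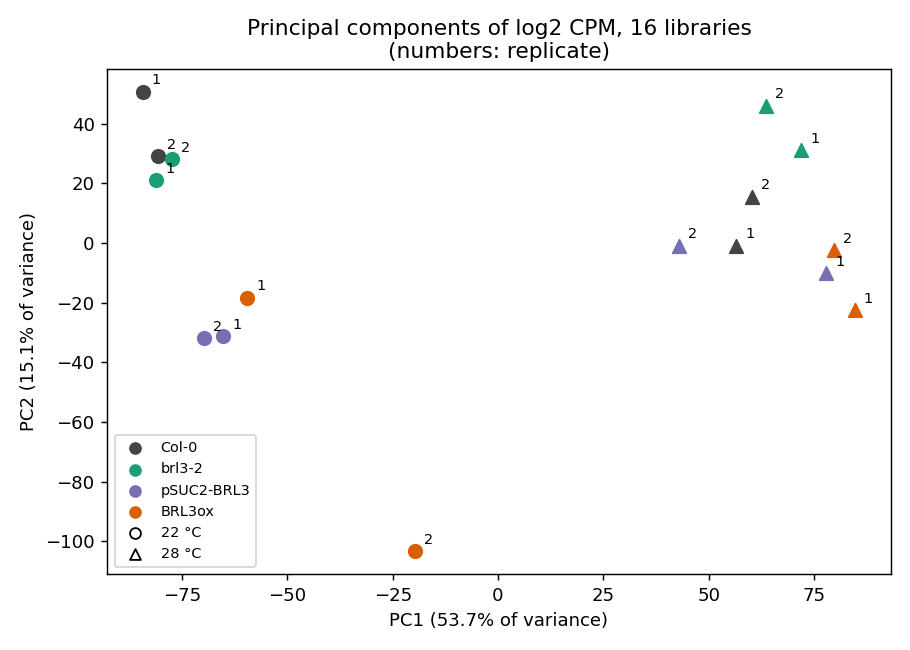
Principal components 1 and 2 of log2 CPM for the 16 libraries (axes: component scores, with the share of variance in percent), with colours for genotypes, circles for 22 °C, triangles for 28 °C and numbers for replicates. Replicate 2 of BRL3ox at 22 °C sits at -103 on component 2.

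The edited gene was read first. BRL3 (AT3G13380) lies on the plus strand of chromosome 3, from 4346330 to 4350939 of TAIR10.1, and its single annotated transcript has 2 exons. In Col-0 BRL3 was measured at 15.003 ± 6.39 CPM at 22 °C and 25.8 ± 4.16 CPM at 28 °C, a log2 difference of 0.78 that missed the threshold (SE 0.30, adjusted p = 0.0533). In brl3-2 it stood at 0.661 ± 0.184 and 0.885 ± 0.215 CPM, lower than in Col-0 by 22.5-fold at 22 °C (log2 -4.49, SE 0.40, adjusted p = 0.0035) and by 28.9-fold at 28 °C (log2 -4.85, SE 0.37, adjusted p = 0.000686). The call at 22 °C was lost when replicate 1 of brl3-2 (log2 -4.24) or replicate 2 of brl3-2 (log2 -4.81) was left out. pSUC2-BRL3 had 52.4 ± 19.5 CPM at 22 °C and 174 ± 5.38 CPM at 28 °C, above Col-0 at both temperatures (log2 1.80, adjusted p = 0.00778, and log2 2.76, adjusted p = 0.00343). The call at 28 °C was lost without replicate 1 of Col-0 (log2 2.60). BRL3ox had 766 ± 71.8 and 2332 ± 206 CPM, 51.0-fold and 90.3-fold above Col-0 (adjusted p = 4.14e-05 and adjusted p = 1.32e-05). BRL3 rose from 22 °C to 28 °C in both transgenic lines, by 1.74 on the log2 scale in pSUC2-BRL3 (adjusted p = 0.00121) and 1.61 in BRL3ox (adjusted p = 0.00181). The BRL3 response to temperature was not shown to differ between genotypes (interaction adjusted p between 0.246 and 0.789). Endogenous and transgene reads cannot be told apart in these counts.

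**Figure D2:**
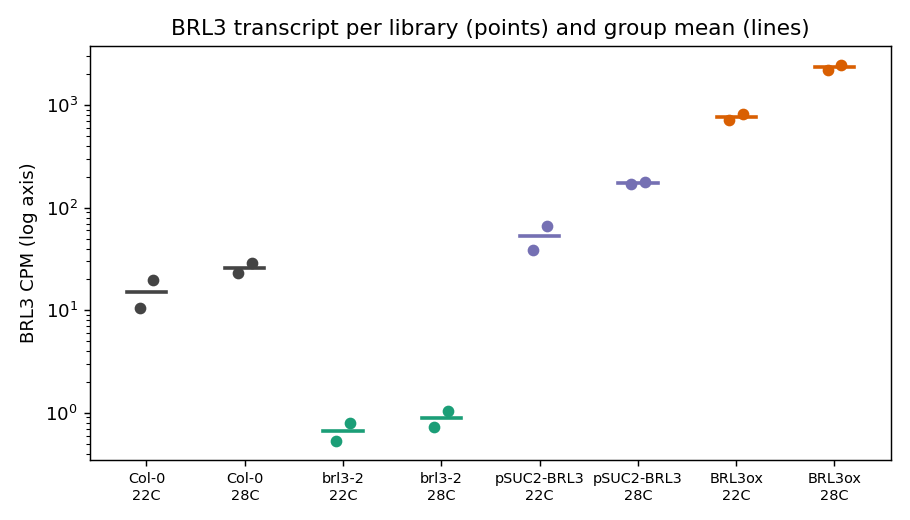
BRL3 expression in CPM on a log axis, with a point per library and a line at each group mean, for the 4 genotypes at 22 °C and 28 °C. Means run from 0.661 CPM in brl3-2 at 22 °C to 2332 CPM in BRL3ox at 28 °C.

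The first comparison asked how warmth changed the wild-type hypocotyl. At 28 °C Col-0 had less RNA of pigment, photosynthesis and cell division genes. It had more RNA of genes for warmth-induced elongation, auxin response and brassinosteroid perception. Both statements rest on list calls, of which 0 held with an estimated correlation. In all 4445 genes rose and 4773 fell, and 12233 changed without the 2 doubted libraries (6193 rose and 6056 fell without the other pair). The flavonoid and anthocyanin list moved most: 17 of 17 fell (median -4.49, 17 over the list alone, adjusted p = 1.67e-10, adjusted p = 0.184 with an estimated correlation). In it DFR (AT5G42800), dihydroflavonol reductase, changed by -7.18 (SE 0.74, adjusted p = 5.35e-05) and TT4 (AT5G13930), chalcone synthase, by -6.32. Among photosynthesis genes 18 of 22 fell, including the Rubisco subunit gene RBCS1A (AT1G67090) at -2.48 and the antenna gene CAB1 (AT1G29930) at -1.56 (median -1.01, 18 over the list alone, adjusted p = 6.07e-07, adjusted p = 0.369 with an estimated correlation). Photosynthesis genes held 13.8% to 20.7% of counts in the libraries at 22 °C and 7.57% to 11.5% at 28 °C. Of cell cycle genes 12 of 17 fell, such as CYCB1;1 (AT4G37490) at -2.47 and CYCA1;1 (AT1G44110) at -2.29 (median -1.38, 14 over the list alone, adjusted p = 4.9e-06, adjusted p = 0.184 with an estimated correlation). Of root markers 3 of 6 fell, PHT1;4 (AT2G38940) by -1.90 among them (median -1.59, 3 over the list alone, adjusted p = 0.0438, adjusted p = 0.369 with an estimated correlation). The root call was lost without replicate 1 at 22 °C (0.115) or replicate 2 at 28 °C (0.107).

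In the PIF4 pathway, the transcriptional route of the warmth response, 14 rose and 2 fell of 24 (median 1.53, 16 over the list alone, adjusted p = 4.9e-06, adjusted p = 0.184 with an estimated correlation). The auxin biosynthesis gene YUC8 (AT4G28720) rose by 4.02 and HFR1 (AT1G02340) by 3.45. Of auxin response genes 11 rose and 1 fell of 17, with WES1 (AT4G27260) at 1.58 and IAA6 (AT1G52830) at 3.24 (median 0.88, 12 over the list alone, adjusted p = 0.00237, adjusted p = 0.369 with an estimated correlation). The brassinosteroid receptor genes BRI1 (AT4G39400) and BRL1 (AT1G55610) rose by 1.34 and 1.82, and in their list 3 of 5 rose (median 0.84, 5 over the list alone, adjusted p = 0.00385, adjusted p = 0.184 with an estimated correlation). Of brassinosteroid biosynthesis genes 6 rose and 1 fell of 10, ROT3 (AT4G36380) by 1.06 and DWF4 (AT3G50660) by 1.39 (median 0.69, 7 over the list alone, adjusted p = 0.0423, adjusted p = 0.425 with an estimated correlation). This last call was lost without replicate 1 at 22 °C (0.0775) or replicate 1 at 28 °C (0.0607). Lists called in no comparison were gibberellin (5 rose and 4 fell of 18 here), expansins and xyloglucan enzymes (4 and 5 of 22) and the clock (5 and 3 of 15). Clock phase was not separated from warmth (Col-0 LHY: 744 to 124 CPM).

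The largest single rises in Col-0 were in RTFL21 (AT1G67265), ENODL1 (AT5G53870) (5.93), the hydroxyjasmonate sulfotransferase gene ST2A (AT5G07010) (5.32) and the ethylene synthesis gene ACS8 (AT4G37770) (4.68). The wall genes ATPMEPCRD (AT2G43050) (4.57) and XTH15 (AT4G14130) (4.55) and the lipid enzyme genes ADS1 (AT1G06080) (4.27) and FAR1 (AT5G22500) (4.25) followed. RTFL21 had 2 counts at 22 °C, so its rise is a ratio of 130 (95% counting interval 35.7 to 1075). Such intervals cover counting error only. The glucosinolate gene CYP79F1 (AT1G16410) had 0 counts at 28 °C and fell at least 207-fold. BCAT4 (AT3G19710), of the same pathway, fell by a ratio of 355 (63.0 to 14103) and the anthocyanin gene LDOX (AT4G22880) by 214 (58.5 to 1775). The iron regulator gene BHLH100 (AT2G41240) fell by 203 (55.5 to 1686) and the defence gene PR5 (AT1G75040) by 175 (47.8 to 1455). The early light-induced genes ELIP1 (AT3G22840) (-7.24) and ELIP2 (AT4G14690) (-6.96) fell with them. The 15 genes of this paragraph and DFR kept their calls when any 1 library was left out. The count of changed genes moved to 6054 without replicate 1 at 22 °C and to 6066 without replicate 2 at 28 °C. The simulated recovery was 40% (2-fold) and 87% (4-fold) of changes put in. Genes with paralogs or with overlapping or antisense partners are uncertain, because the strand setting is not stated.

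The second comparison asked whether the mutant still responded to warmth. In brl3-2 5287 genes rose and 4768 fell (4835 and 4903 on nuclear protein-coding genes, 12894 changed without the 2 doubted libraries). Of the lists called in Col-0, photosynthesis, flavonoids and cell cycle were again called down and receptors and the PIF4 pathway up. Auxin response (8 rose and 1 fell of 17, adjusted p = 0.0799), brassinosteroid biosynthesis (4 of 10 rose, adjusted p = 0.0928) and root (3 of 6 fell, adjusted p = 0.0896) were not called here, which by itself shows no difference from Col-0. Of photosynthesis genes 20 of 22 fell, RBCS1A by -2.72 and CAB1 by -1.79 (median -1.23, 22 over the list alone, adjusted p = 2.6e-09, adjusted p = 0.553 with an estimated correlation). Among flavonoid genes 12 of 17 fell, with LDOX at -6.50 and TT4 at -5.06 (median -4.17, 13 over the list alone, adjusted p = 2.41e-05, adjusted p = 0.553 with an estimated correlation). Of cell cycle genes 14 of 17 fell, CYC1BAT (AT5G06150) by -1.80 and CYCB1;1 by -2.14 (median -1.34, 15 over the list alone, adjusted p = 8.14e-05, adjusted p = 0.553 with an estimated correlation). Of receptor genes 4 of 5 rose, BRI1 by 1.18 and BAK1 (AT4G33430) by 1.15 (median 1.15, 4 over the list alone, adjusted p = 0.0258, adjusted p = 0.438 with an estimated correlation). Of PIF4-pathway genes 9 rose and 2 fell of 24, HFR1 by 2.84 and YUC8 by 3.15 (median 0.73, 11 over the list alone, adjusted p = 0.042, adjusted p = 0.553 with an estimated correlation), a call lost without replicate 2 at 22 °C (0.0605). Top rises were the flagellin receptor gene FLS2 (AT5G46330) (6.12), FAR1 (5.31), the clock gene PRR5 (AT5G24470) (5.17), ST2A (4.91) and ADS1 (4.84). The iron transporter gene IRT1 (AT4G19690) fell at least 121-fold and DFR by a ratio of 293 (99.7 to 1426). ELIP2 (-5.97) and ELIP1 (-5.83) fell as in Col-0. All 10 named genes kept their calls whichever library was left out. The simulated recovery was 40% (2-fold) and 87% (4-fold).

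The third comparison asked how the line with BRL3 in the phloem responded to warmth. In pSUC2-BRL3 4028 genes rose and 3992 fell (3705 and 4145 on nuclear protein-coding genes, 8677 changed without the 2 doubted libraries, 10427 without the other pair). The photosynthesis, flavonoid and cell cycle lists were called down, and the receptor and cold-regulated lists up. Lists called in Col-0 but not here, which by itself shows no difference, were the PIF4 pathway (10 rose and 4 fell of 24, adjusted p = 0.213), auxin response (2 rose and 3 fell of 17, adjusted p = 0.839), brassinosteroid biosynthesis (3 of 10 rose, adjusted p = 0.145) and root (1 rose and 1 fell of 6, adjusted p = 0.599). Of photosynthesis genes 22 of 22 fell, RBCS1A by -2.46 and RBCS3B (AT5G38410) by -1.85 (median -1.36, 22 over the list alone, adjusted p = 3.67e-13, adjusted p = 0.598 with an estimated correlation). Among flavonoid genes 12 of 17 fell, with LDOX at -4.91 and UGT75C1 (AT4G14090) at -3.98 (median -3.54, 13 over the list alone, adjusted p = 1.05e-05, adjusted p = 0.612 with an estimated correlation). Of cell cycle genes 11 of 17 fell, CYCB1;1 by -1.91 and CDKB2;2 (AT1G20930) by -1.52 (median -0.92, 12 over the list alone, adjusted p = 0.001, adjusted p = 0.612 with an estimated correlation). Of receptor genes 4 of 5 rose, including BRL3, with BRL1 by 1.74 and BAK1 by 0.80 (median 0.80, 5 over the list alone, adjusted p = 0.0172, adjusted p = 0.401 with an estimated correlation). Of cold-regulated genes 10 of 14 rose, with COR47 (AT1G20440) at 2.34 and LTI78 (AT5G52310) at 4.98 (median 3.096, 12 over the list alone, adjusted p = 0.001, adjusted p = 0.615 with an estimated correlation). LTI78, also called RD29A, stood at 596 CPM in replicate 1 and 47.1 CPM in replicate 2 at 28 °C. Top rises were COR15B (AT2G42530) (ratio 920, 165 to 36363.5), the indole metabolism gene CYP71A12 (AT2G30750) (227, 40.5 to 8991), PRR5 (7.32), the blue-light gene FKF1 (AT1G68050) (124, 34.2 to 1029) and the cold regulator gene DREB1A (AT4G25480) (79.8, 27.1 to 389). COR15B stood at 51.8 CPM in replicate 1 and 1.14 CPM in replicate 2 at 28 °C, and CYP71A12, FKF1 and DREB1A at 6.50 ± 5.07, 7.14 ± 8.20 and 6.87 ± 6.69 CPM. IRT1 fell at least 114-fold and the seed storage gene SESA3 (AT4G27160) by 150 (50.7 to 732). DFR (-6.94), ELIP2 (-6.26) and TT4 (-5.92) also fell. CYP71A12, DREB1A and SESA3 lost their calls in at least 1 leave-one-out. The count moved to 4699 without replicate 2 at 22 °C and 4940 without replicate 1 at 28 °C. The simulated recovery was 35% (2-fold) and 87% (4-fold).

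The fourth comparison asked how hypocotyls with general BRL3 overexpression responded to warmth. In BRL3ox 3753 genes rose and 3960 fell (4903 and 4869 without the other pair, 9756 changed without the 2 doubted libraries). Photosynthesis genes fell and most PIF4-pathway genes rose. Lists called in Col-0 but not here, which by itself shows no difference, were flavonoids (2 rose and 6 fell of 17, adjusted p = 0.181), brassinosteroid biosynthesis (1 rose and 2 fell of 10, adjusted p = 0.723) and root (1 rose and 2 fell of 6, adjusted p = 0.691). Of photosynthesis genes 22 of 22 fell, CAB1 by -2.22 and RBCS1A by -2.75 (median -1.80, 22 over the list alone, adjusted p = 1.03e-23, adjusted p = 0.2 with an estimated correlation). Of PIF4-pathway genes 18 rose and 4 fell of 24, HFR1 by 3.02 and SAUR22 (AT5G18050) by 3.69 (median 1.63, 22 over the list alone, adjusted p = 2.24e-05, adjusted p = 0.2 with an estimated correlation). Of auxin response genes 9 of 17 rose, WES1 by 1.21 and IAA29 (AT4G32280) by 2.08 (median 0.79, 9 over the list alone, adjusted p = 0.00593, adjusted p = 0.565 with an estimated correlation), a call lost without replicate 2 at 22 °C (0.162). Of receptor genes 4 of 5 rose, including BRL3, with BRL1 by 2.42 and BAK1 by 0.55 (median 0.55, 4 over the list alone, adjusted p = 0.0266, adjusted p = 0.2 with an estimated correlation), lost without replicate 1 at 22 °C (0.19) or replicate 2 at 22 °C (0.0559). Of cold-regulated genes 7 of 14 rose, LTI78 by 3.32 and KIN2 (AT5G15970) by 2.79 (median 1.67, 8 over the list alone, adjusted p = 0.0266, adjusted p = 0.715 with an estimated correlation), lost without replicate 1 at 22 °C (0.19). Among abscisic acid genes 4 rose and 1 fell of 12, the phosphatase genes ABI1 (AT4G26080) at 1.29 and HAI2 (AT1G07430) at 5.01 rising (median 0.92, 5 over the list alone, adjusted p = 0.0463, adjusted p = 0.715 with an estimated correlation), lost without replicate 1 at 22 °C (0.461), replicate 2 at 22 °C (0.112) or replicate 2 at 28 °C (0.169). Of shoot apex and stomatal genes 1 rose and 8 fell of 13, BASL (AT5G60880) by -1.72 and KNAT1 (AT4G08150) by 1.07 (median -1.16, 9 over the list alone, adjusted p = 0.0426, adjusted p = 0.357 with an estimated correlation), lost without replicate 1 at 22 °C (0.474) or replicate 2 at 22 °C (0.0559). Of cell cycle genes 7 of 17 fell, PCNA2 (AT2G29570) by -0.81 and CYCB1;1 by -1.26 (median -0.72, 9 over the list alone, adjusted p = 0.0463, adjusted p = 0.715 with an estimated correlation), lost without replicate 1 at 22 °C (0.638) or replicate 1 at 28 °C (0.0737). Top rises were ST2A (6.29), ENODL1 (6.18), the galactosidase gene BGAL7 (AT5G20710) (5.62), the peroxidase gene PA2 (AT5G06720) (5.22) and COR15B (4.86). Top falls were ELIP2 (-6.47), MEE3 (AT2G21650) (-5.27), GRP9 (AT2G05440) (-4.98), DOT3 (AT5G10250) (-4.78) and the myrosinase gene TGG2 (AT5G25980) (-4.75). Of the 10 only COR15B lost its call in a leave-one-out. The count moved to 4757 without replicate 1 and 4728 without replicate 2 at 28 °C. The simulated recovery was 44% (2-fold) and 89% (4-fold).

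With warmth 1737 genes rose and 2166 fell in all 4 genotypes. Across tested genes the response of brl3-2 correlated with that of Col-0 at r = 0.792, that of pSUC2-BRL3 at r = 0.700 and that of BRL3ox at r = 0.693. The last fell to r = 0.443 without replicate 1 of BRL3ox at 22 °C. Genes are not independent replicates, so these coefficients carry no test. Shared rises and falls with Col-0 numbered 3263 and 3404 in brl3-2, 2538 and 2839 in pSUC2-BRL3, and 2234 and 2668 in BRL3ox. Independent lists would share 1146 and 1110, 873 and 929, and 814 and 922. Opposite calls numbered 71, 108 and 115. DFR and ELIP2 fell in every genotype, DFR in BRL3ox by only -1.46 (SE 0.48, adjusted p = 0.0323).

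**Figure D3:**
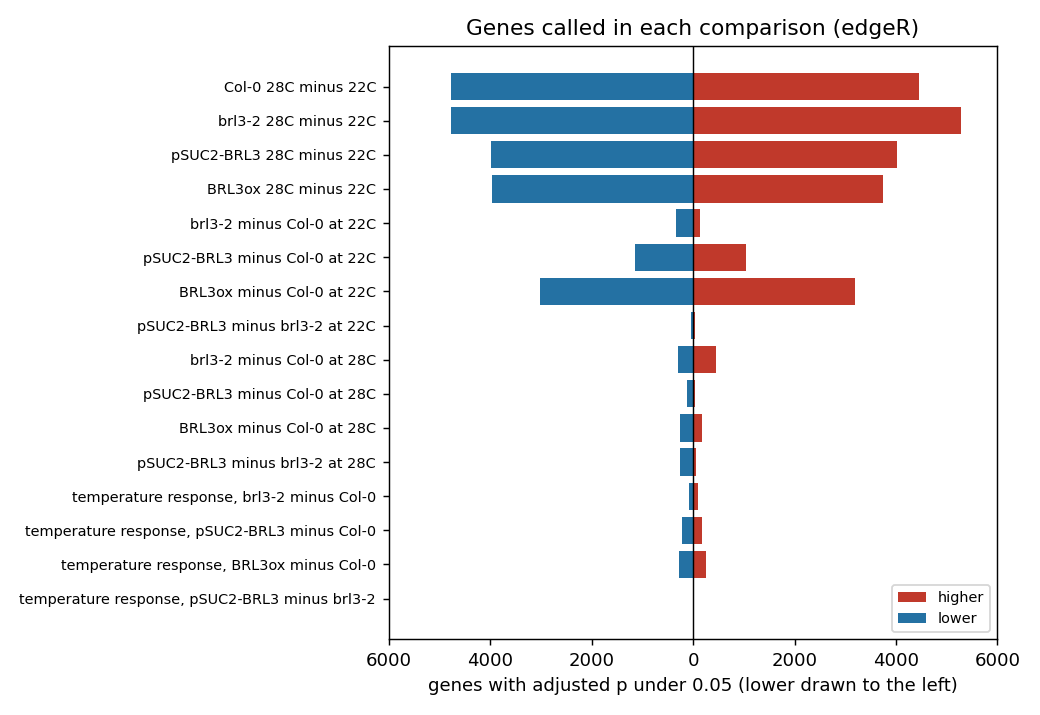
Number of genes called in each comparison (axis: genes), higher to the right and lower to the left. The temperature comparisons reach 5287 higher and 4773 lower.

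At 22 °C the question was how the mutant line differed from Col-0 without warmth. In brl3-2 129 genes were higher and 331 lower than in Col-0 (3433 changed without the 2 doubted libraries). Lower genes were BRL3, the starch gene QQS (AT3G30720) (-3.40), the low-sulfur gene LSU2 (AT5G24660) (-3.00), the sulfate reduction gene APR2 (AT1G62180) (-2.85) and the acid phosphatase gene PAP17 (AT3G17790) (-2.67). Higher were the expansin-like gene EXLA1 (AT3G45970) (2.02), the peroxidase gene PER4 (AT1G14540) (2.01), the immune receptor gene ZAR1 (AT3G50950) (1.69), PTI1-4 (AT2G47060) (1.62) and CAD1 (AT1G29690) (1.57). The auxin response list was called up although 0 of 17 passed (median 0.38, 5 over the list alone, adjusted p = 0.022, adjusted p = 0.834 with an estimated correlation). It was lost without replicate 1 of Col-0 (0.323) or replicate 1 of brl3-2 (0.0699). The jasmonate list was called up, 0 of 18 passed (median 0.43, 0 over the list alone, adjusted p = 0.00426, adjusted p = 0.834 with an estimated correlation). It was lost without replicate 2 of Col-0 (0.104). The flavonoid list was called down, 0 of 17 passed (median -0.62, 1 over the list alone, adjusted p = 0.0287, adjusted p = 0.834 with an estimated correlation). It was lost without replicate 1 of Col-0 (0.272) or replicate 1 of brl3-2 (0.168). None of the 10 named genes kept its call in every leave-one-out. Without replicate 1 or 2 of Col-0 the count was 2 or 86, and without replicate 1 or 2 of brl3-2 it was 0. With all libraries unadjusted p was below 0.05 for 3808 genes. DESeq2 called 1277 genes, and the simulated recovery was 34% (2-fold) and 91% (4-fold).

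The next question was what pSUC2-BRL3 changed from Col-0 at 22 °C. In it 1035 genes were higher and 1141 lower, which turned to 1183 and 949 on nuclear protein-coding genes (6594 changed without the 2 doubted libraries). The heat shock and flavonoid lists were called down, and the auxin and PIF4-pathway lists up. Of auxin response genes 7 of 17 were higher, IAA29 by 1.95 and IAA6 by 2.36 (median 0.44, 7 over the list alone, adjusted p = 8.93e-05, adjusted p = 0.407 with an estimated correlation). In the PIF4 pathway 5 of 24 were higher, PRE1 (AT5G39860) by 1.24 and YUC8 by 1.69 (median 0.59, 6 over the list alone, adjusted p = 0.000189, adjusted p = 0.407 with an estimated correlation). Of brassinosteroid signalling genes 3 of 12 were higher, the kinase gene BIN2 (AT4G18710) by 0.83 and CYP72C1 (AT1G17060) by 1.18 (median 0.49, 6 over the list alone, adjusted p = 0.00484, adjusted p = 0.326 with an estimated correlation). Of heat shock genes 8 of 26 were lower, HSP101 (AT1G74310) by -2.21 and the regulator gene HSFA2 (AT2G26150) by -3.77 (median -0.98, 10 over the list alone, adjusted p = 0.000189, adjusted p = 0.407 with an estimated correlation). Of flavonoid genes 6 of 17 were lower, TT5 (AT3G55120) by -2.12 and the anthocyanin regulator gene PAP1 (AT1G56650) by -3.15 (median -0.80, 7 over the list alone, adjusted p = 8.93e-05, adjusted p = 0.468 with an estimated correlation). Of cell cycle genes 1 of 17 was lower, TSO2 (AT3G27060) by -1.54 (median -0.64, 3 over the list alone, adjusted p = 0.000754, adjusted p = 0.407 with an estimated correlation). The photosynthesis list was called up although 0 of 22 passed (median 0.45, 0 over the list alone, adjusted p = 0.000189, adjusted p = 0.525 with an estimated correlation). Of jasmonate genes 2 of 18 were lower, TIFY10B (AT1G74950) by -0.68 and JAZ5 (AT1G17380) by -3.37 (median -0.75, 5 over the list alone, adjusted p = 0.0226, adjusted p = 0.563 with an estimated correlation), lost without replicate 1 of Col-0 (0.173) or replicate 1 of pSUC2-BRL3 (0.0634). Higher were P1R3 (AT3G29370) (4.28), the chaperone partner gene Fes1B (AT3G53800) (3.36), WRI4 (AT1G79700) (2.48), the 14-3-3 gene GRF11 (AT1G34760) (2.28) and the shade gene PAR1 (AT2G42870) (2.27). Lower were LSU2 (-5.21), APR1 (AT4G04610) (-4.47), PAP17 (-4.37), APR3 (AT4G21990) (-4.09) and APR2 (-4.000). P1R3, GRF11, LSU2, PAP17 and APR2 kept their calls in every leave-one-out. The count was 92 or 914 without replicate 1 or 2 of Col-0, and 473 or 71 without replicate 1 or 2 of pSUC2-BRL3. The simulated recovery was 29% (2-fold) and 88% (4-fold).

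The same question for BRL3ox at 22 °C gave 3189 genes higher and 3008 lower than in Col-0 (1564 and 1952 without the 2 doubted libraries). The flavonoid, heat shock and cell cycle lists were called down. The homeobox gene HB17 (AT2G01430) (6.06) was higher, as was BRL3 itself. Of flavonoid genes 9 of 17 were lower, TT5 by -2.70 and UGT78D2 by -1.99 (median -1.91, 11 over the list alone, adjusted p = 2.17e-07, adjusted p = 0.39 with an estimated correlation). Of cell cycle genes 8 of 17 were lower, TSO2 by -1.80 and CYCB1;1 by -1.17 (median -0.84, 10 over the list alone, adjusted p = 0.000377, adjusted p = 0.39 with an estimated correlation). Of heat shock genes 8 of 26 were lower, HSP101 by -1.98 and HSP90.1 (AT5G52640) by -1.93 (median -0.91, 8 over the list alone, adjusted p = 0.00332, adjusted p = 0.657 with an estimated correlation). Of photosynthesis genes 10 were higher and 1 were lower of 22, CAB3 by 0.98 and LHCA4 (AT3G47470) by 1.04 upward (median 0.63, 15 over the list alone, adjusted p = 0.00142, adjusted p = 0.829 with an estimated correlation). Of receptor genes 3 were higher and 1 were lower of 5, BRL3 by 5.67 and BRI1 by 0.69 upward and BRL1 by -1.105, with BRL3 in the mean of 1.08 (median 0.57, 4 over the list alone, adjusted p = 0.00931, adjusted p = 0.39 with an estimated correlation), lost without replicate 1 of BRL3ox (0.123). Higher were Fes1B (4.61), CCL (AT3G26740) (4.41) and P1R3 (4.32). CCL stood at 74.2 CPM in replicate 1 and 1016 CPM in replicate 2. CYP79F1 was lower by a ratio of 377 (67.2 to 14928), and FMO GS-OX3 (AT1G62560) (-5.84) and MYB29 (AT5G07690) (-4.48) of the same pathway were lower too. LSU2 (-4.94) and PAP17 (-4.56) were lower as in the other lines. CCL, CYP79F1 and MYB29 lost their calls in at least 1 leave-one-out. The count was 853 or 2960 without replicate 1 or 2 of Col-0, and 10577 or 2725 without replicate 1 or 2 of BRL3ox. The simulated recovery was 42% (2-fold) and 90% (4-fold).

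The comparison of pSUC2-BRL3 with brl3-2 at 22 °C came next. In pSUC2-BRL3 31 genes, BRL3 among them, were higher and 32 lower than in brl3-2 (2134 and 1581 without the 2 doubted libraries). The jasmonate and heat shock lists were called down and the auxin list up. Higher were BRL3 (6.29 (SE 0.41, adjusted p = 0.000127)), P1R3 (1.87), GATL7 (AT3G62660) (1.498), the expansin gene EXPA11 (AT1G20190) (1.48) and the ethylene F-box gene EBF2 (AT5G25350) (1.38). Lower were the ethylene synthesis gene ACS7 (AT4G26200) (-3.36), WRKY18 (AT4G31800) (-3.29), PER4 (-2.62), the glucosinolate transporter gene GTR1 (AT3G47960) (-2.27) and ATPMEPCRB (AT4G02330) (-2.22). Of jasmonate genes 1 of 18 was lower, OPR3 by -1.96 (median -0.96, 8 over the list alone, adjusted p = 9.19e-10, adjusted p = 0.168 with an estimated correlation). Of heat shock genes 1 of 26 was lower, HSF4 (AT4G36990) by -1.37 (median -0.91, 1 over the list alone, adjusted p = 2.22e-05, adjusted p = 0.246 with an estimated correlation). Of receptor genes 1 of 5 was higher, BRL3, and the call follows it (mean 1.22, median 0.08, 2 over the list alone, adjusted p = 0.000345, adjusted p = 0.0751 with an estimated correlation). Of auxin response genes 1 of 17 was higher, ATAUX2-11 (AT5G43700) by 1.17 (median 0.29, 2 over the list alone, adjusted p = 0.0169, adjusted p = 0.551 with an estimated correlation), lost without replicate 2 of brl3-2 (0.0532) or replicate 2 of pSUC2-BRL3 (0.134).

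In the same comparison 8 lists were called with no member past the threshold. Brassinosteroid signalling was called up, 0 of 12 passed (median 0.35, 4 over the list alone, adjusted p = 0.00924, adjusted p = 0.162 with an estimated correlation). The PIF4 pathway was called up, 0 of 24 passed (median 0.61, 10 over the list alone, adjusted p = 0.000417, adjusted p = 0.212 with an estimated correlation). Photosynthesis was called up, 0 of 22 passed (median 0.32, 0 over the list alone, adjusted p = 0.0014, adjusted p = 0.551 with an estimated correlation), lost without replicate 2 of brl3-2 (0.0977). Cell cycle genes were called down, 0 of 17 passed (median -0.55, 0 over the list alone, adjusted p = 2.22e-05, adjusted p = 0.168 with an estimated correlation). Flavonoid genes were called down, 0 of 17 passed (median -0.57, 1 over the list alone, adjusted p = 0.0084, adjusted p = 0.551 with an estimated correlation), lost without replicate 2 of brl3-2 (0.0921). Salicylic acid defence was called down, 0 of 11 passed (median -1.07, 1 over the list alone, adjusted p = 0.00139, adjusted p = 0.162 with an estimated correlation). Cold-regulated genes were called down, 0 of 14 passed (median -0.75, 0 over the list alone, adjusted p = 0.0123, adjusted p = 0.551 with an estimated correlation). Xylem genes were called down, 0 of 20 passed (median -0.35, 0 over the list alone, adjusted p = 0.0274, adjusted p = 0.551 with an estimated correlation), lost without replicate 2 of brl3-2 (0.345) or replicate 1 of pSUC2-BRL3 (0.249). Only BRL3 of the 10 named genes kept its call in every leave-one-out. The count was 1 without replicate 1 or 2 of brl3-2 and 2 without replicate 1 or 2 of pSUC2-BRL3. DESeq2 called 953 genes, and the simulated recovery was 34% (2-fold) and 84% (4-fold).

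At 28 °C the question was how the mutant line differed from Col-0 in warm-grown hypocotyls. In brl3-2 449 genes were higher and 294 lower than in Col-0, a balance that turned in other settings (1473 and 1485 without the 2 doubted libraries, 11 and 32 or 56 and 60 without replicate 1 or 2 of Col-0). The jasmonate and salicylic acid lists were called up and the heat shock list down. Of jasmonate genes 6 of 18 were higher, the lipoxygenase gene LOX3 (AT1G17420) by 3.96 and AOC2 (AT3G25770) by 1.49 (median 1.49, 14 over the list alone, adjusted p = 5.85e-12, adjusted p = 0.117 with an estimated correlation). Of salicylic acid genes 2 of 11 were higher, SARD1 (AT1G73805) by 3.40 and EDS1 (AT3G48090) by 1.09 (median 1.12, 4 over the list alone, adjusted p = 1.94e-05, adjusted p = 0.0584 with an estimated correlation). Of heat shock genes 7 of 26 were lower, the coactivator gene MBF1C (AT3G24500) by -3.93 and HSP101 by -1.99 (median -1.27, 12 over the list alone, adjusted p = 4.8e-15, adjusted p = 0.0584 with an estimated correlation). Of PIF4-pathway genes 1 were higher and 2 were lower of 24, HFR1 by -1.45 and TAA1 (AT1G70560) by 1.19 (median -0.73, 10 over the list alone, adjusted p = 0.000974, adjusted p = 0.247 with an estimated correlation). Of osmoprotectant genes 1 of 15 was lower, GolS1 (AT2G47180) by -1.65 (median -0.21, 4 over the list alone, adjusted p = 0.00421, adjusted p = 0.0584 with an estimated correlation). Of receptor genes 1 of 5 was lower, BRL3, and the call follows the mean of -0.90 (median 0.03, 1 over the list alone, adjusted p = 0.0279, adjusted p = 0.117 with an estimated correlation), lost without replicate 2 of brl3-2 (0.104). Higher were LOX4 (AT1G72520) (5.18), WRKY53 (AT4G23810) (4.37), DAR3 (AT5G66640) (4.27), WRKY30 (AT5G24110) (4.02) and MDHAR (AT3G09940) (3.996). Lower were BRL3, QQS (-4.002), the mitochondrial chaperone gene HSP23.5 (AT5G51440) (-2.45) and TIN1 (AT5G64510) (-2.41). Of the 10, BRL3, QQS and MBF1C kept their calls in every leave-one-out. The count was 43 or 116 without replicate 1 or 2 of Col-0, and 358 or 52 without replicate 1 or 2 of brl3-2. DESeq2 called 1458 genes, and the simulated recovery was 45% (2-fold) and 90% (4-fold).

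The question for pSUC2-BRL3 at 28 °C was the same. In it 47 genes were higher and 129 lower than in Col-0 (720 changed without the 2 doubted libraries, 2145 without the other pair). The heat shock list was called down. Of heat shock genes 8 of 26 were lower, MBF1C by -3.47 and HSP90.1 by -3.38 (median -1.05, 12 over the list alone, adjusted p = 1.43e-22, adjusted p = 0.0552 with an estimated correlation). HSP70 (AT3G12580) stood at 390 and 350 CPM in Col-0 and at 23.7 and 13.7 CPM here (-4.31). Of brassinosteroid biosynthesis genes 1 of 10 was lower, BR6OX2 (AT3G30180) by -1.25 (median -0.33, 3 over the list alone, adjusted p = 0.000644, adjusted p = 0.275 with an estimated correlation). Higher were the expansin gene EXPA16 (AT3G55500) (2.92), BRL3, the amino acid transporter gene LHT1 (AT5G40780) (2.198), GLR3.5 (AT2G32390) (2.13) and OEP6 (AT3G63160) (1.85). In pSUC2-BRL3 EXPA16 stood at 19.5 ± 16.0 CPM and OEP6 at 63.9 ± 45.3 CPM. Lower were also ROF2 (AT5G48570) (-3.82) and HSP23.5 (-3.70). Other lists were called with no member past the threshold. Xylem genes were called down, 0 of 20 passed (median -0.53, 0 over the list alone, adjusted p = 1.86e-05, adjusted p = 0.275 with an estimated correlation). The PIF4 pathway was called down, 0 of 24 passed (median -0.48, 0 over the list alone, adjusted p = 0.00377, adjusted p = 0.275 with an estimated correlation), lost without replicate 1 of Col-0 (0.0769) or replicate 2 of pSUC2-BRL3 (0.0979). Auxin response was called down, 0 of 17 passed (median -0.40, 6 over the list alone, adjusted p = 0.0214, adjusted p = 0.478 with an estimated correlation), lost without replicate 1 of Col-0 (0.0769) or replicate 2 of pSUC2-BRL3 (0.144). Cold-regulated genes were called up, 0 of 14 passed (median 2.31, 9 over the list alone, adjusted p = 5.99e-06, adjusted p = 0.275 with an estimated correlation), lost without replicate 1 of pSUC2-BRL3 (0.787). Salicylic acid defence was called up, 0 of 11 passed (median 1.08, 2 over the list alone, adjusted p = 0.00177, adjusted p = 0.189 with an estimated correlation), lost without replicate 2 of pSUC2-BRL3 (0.0879). The abscisic acid list was called up, 0 of 12 passed (median 0.60, 0 over the list alone, adjusted p = 0.0285, adjusted p = 0.538 with an estimated correlation). It was lost without replicate 1 of Col-0 (0.124), replicate 2 of Col-0 (0.0807) or replicate 1 of pSUC2-BRL3 (0.231), the last with the direction reversed. HSP23.5 and MBF1C kept their calls in every leave-one-out. The count was 14 or 34 without replicate 1 or 2 of Col-0, and 42 or 294 without replicate 1 or 2 of pSUC2-BRL3. DESeq2 called 673 genes, and the simulated recovery was 49% (2-fold) and 94% (4-fold).

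For BRL3ox at 28 °C 170 genes were higher and 254 lower than in Col-0 (3488 changed without the 2 doubted libraries). The brassinosteroid biosynthesis and heat shock lists were called down. Of brassinosteroid biosynthesis genes 5 of 10 were lower, the oxidase gene BR6OX2 by -3.35 and DWF4 by -2.04 (median -0.73, 8 over the list alone, adjusted p = 1.53e-13, adjusted p = 0.0514 with an estimated correlation). Of heat shock genes 8 of 26 were lower, MBF1C by -3.50 and HSP23.5 by -3.104 (median -0.62, 12 over the list alone, adjusted p = 7.36e-09, adjusted p = 0.187 with an estimated correlation). Of jasmonate genes 2 of 18 were higher, AOC2 by 2.27 and AOC1 (AT3G25760) by 1.45 (median 0.45, 2 over the list alone, adjusted p = 0.00107, adjusted p = 0.503 with an estimated correlation), lost without replicate 2 of BRL3ox (0.214). Of flavonoid genes 1 of 17 was higher, DFR by 4.97 (median 1.35, 7 over the list alone, adjusted p = 0.00107, adjusted p = 0.503 with an estimated correlation, and 0.89 as median with bounds for 0 counts). Of phloem genes 1 of 19 was higher, the sugar exporter gene SWEET12 (AT5G23660) by 1.09 (median 0.35, 5 over the list alone, adjusted p = 0.00107, adjusted p = 0.187 with an estimated correlation). Of salicylic acid genes 1 of 11 was higher, SARD1 by 3.92 (median 0.53, 3 over the list alone, adjusted p = 0.00693, adjusted p = 0.187 with an estimated correlation), lost without replicate 1 of Col-0 (0.0839). Of receptor genes 1 of 5 was higher, BRL3, and the call follows the mean of 1.07 (median -0.35, 3 over the list alone, adjusted p = 0.0159, adjusted p = 0.187 with an estimated correlation), lost without replicate 1 of Col-0 (0.0893). Higher were HB17 (7.25), BRL3 and the ethylene synthesis genes ACS5 (AT5G65800) (4.17) and ACS4 (AT2G22810) (3.27). Lower were QQS (-5.15), HSP70 (-4.16) and ACS11 (AT4G08040) (-3.38).

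In this comparison 4 lists were called with no member past the threshold. Cold-regulated genes were called up, 0 of 14 passed (median 1.54, 0 over the list alone, adjusted p = 0.000128, adjusted p = 0.445 with an estimated correlation). Xylem genes were called down, 0 of 20 passed (median -0.42, 0 over the list alone, adjusted p = 0.00107, adjusted p = 0.493 with an estimated correlation). Photosynthesis was called down, 0 of 22 passed (median -0.24, 0 over the list alone, adjusted p = 0.00232, adjusted p = 0.594 with an estimated correlation), lost without replicate 1 of Col-0 (0.0523). The abscisic acid list was called up, 0 of 12 passed (median 0.47, 2 over the list alone, adjusted p = 0.0212, adjusted p = 0.571 with an estimated correlation), lost without replicate 1 of Col-0 (0.138), replicate 2 of Col-0 (0.0555) or replicate 2 of BRL3ox (0.241). HB17, BRL3, AOC2, QQS and BR6OX2 kept their calls in every leave-one-out. The count was 43 or 57 without replicate 1 or 2 of Col-0, and 55 or 29 without replicate 1 or 2 of BRL3ox. DESeq2 called 1168 genes, and the simulated recovery was 35% (2-fold) and 96% (4-fold).

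The comparison of pSUC2-BRL3 with brl3-2 at 28 °C came next. Here 68 genes were higher and 262 lower than in brl3-2, a balance that other settings did not keep (682 and 750 without the 2 doubted libraries, 1209 and 1452 without the other pair, 45 and 33 without replicate 2 of pSUC2-BRL3). The jasmonate list was called down. Of jasmonate genes 4 of 18 were lower, LOX3 by -3.78 and LOX4 by -5.26 (median -1.59, 15 over the list alone, adjusted p = 3.07e-10, adjusted p = 0.412 with an estimated correlation). Of auxin response genes 2 of 17 were lower, WES1 by -0.91 and IAA30 (AT3G62100) by -1.15 (median -0.51, 2 over the list alone, adjusted p = 0.00272, adjusted p = 0.499 with an estimated correlation). Higher were BRL3 (7.61 (SE 0.41, adjusted p = 1.34e-05)), OFP13 (AT5G04820) (1.35), BBX15 (AT1G25440) (1.29), KNAT4 (AT5G11060) (1.08) and PUT1 (AT1G31820) (1.08). Lower were also WRKY30 (-4.12), DAR3 (-3.81) and BBX32 (AT3G21150) (-3.28). Xylem genes were called down, 0 of 20 passed (median -0.54, 0 over the list alone, adjusted p = 0.000144, adjusted p = 0.499 with an estimated correlation). Photosynthesis was called up, 0 of 22 passed (median 0.31, 0 over the list alone, adjusted p = 0.00224, adjusted p = 0.582 with an estimated correlation), lost without replicate 2 of pSUC2-BRL3 (0.945). Cold-regulated genes were called up, 0 of 14 passed (median 1.35, 0 over the list alone, adjusted p = 0.0194, adjusted p = 0.582 with an estimated correlation). This call was lost without replicate 1 of brl3-2 (0.144) or replicate 1 of pSUC2-BRL3 (0.0889), the last with the direction reversed. Only BRL3 kept its call in every leave-one-out. The count was 211 or 1 without replicate 1 or 2 of brl3-2, and 3 or 78 without replicate 1 or 2 of pSUC2-BRL3. DESeq2 called 1055 genes, and the simulated recovery was 36% (2-fold) and 86% (4-fold).

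**Figure D4:**
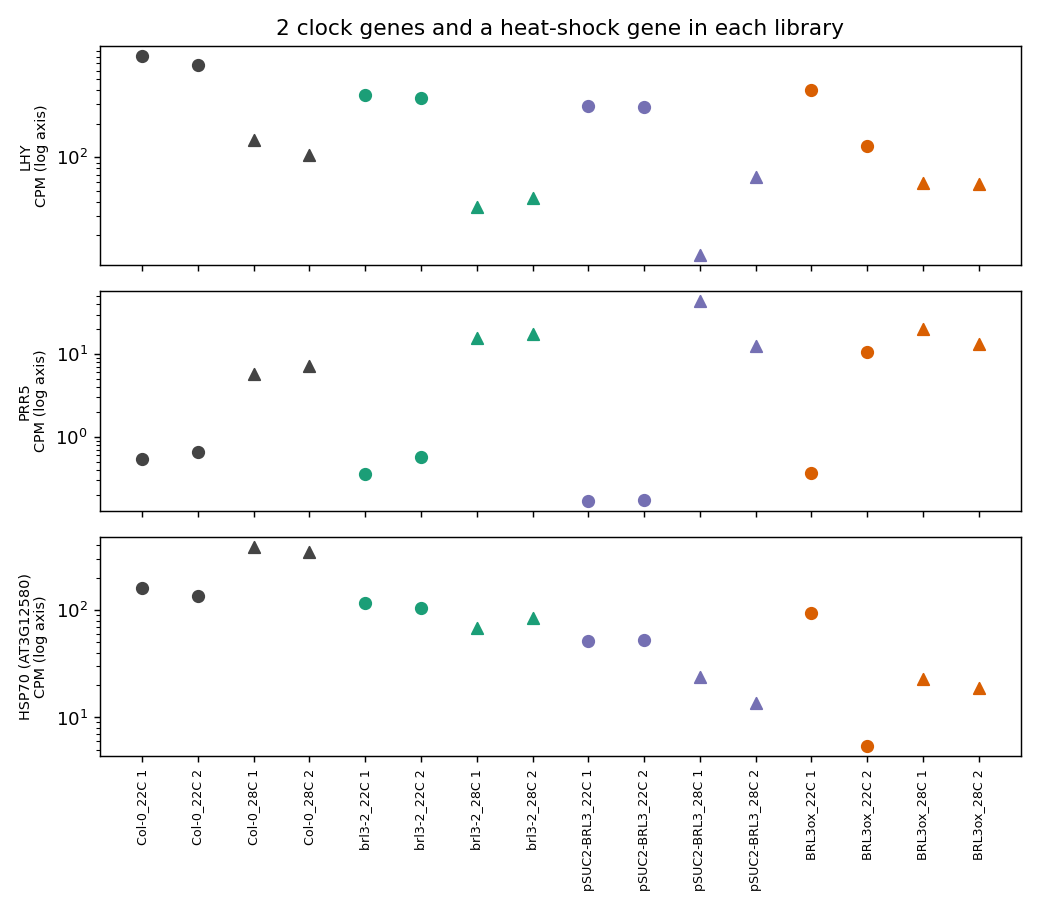
Expression of the clock genes LHY and PRR5 and of the heat shock gene HSP70 in CPM on a log axis, with a point per library. HSP70 at 28 °C is 390 and 350 CPM in Col-0 and at most 84.7 CPM in the other genotypes.

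The 3 lines shared changes from Col-0. At 22 °C 59 genes were higher and 176 lower in all 3, the lower ones including APR2, LSU2, PAP17, QQS and BR6OX2. At 28 °C 8 were higher, AOC2 and GLR3.5 among them, and 54 lower, with HSP101, HSP23.5, HSP90.1, MBF1C, QQS and GolS1. In the same direction brl3-2 and pSUC2-BRL3 shared 304 genes at 22 °C, brl3-2 and BRL3ox 266, and pSUC2-BRL3 and BRL3ox 1754. At 28 °C these numbers were 80, 126 and 117. Without the 2 doubted libraries the 6 overlaps were 2276, 1316, 2723, 355, 916 and 433, and with 1 library left out they ran from 0 to 107, 0 to 1626, 69 to 4706, 6 to 113, 13 to 51 and 10 to 188. Independent lists would share at most 167 genes in either direction, and at most 7 genes were called in opposite directions. Part of each overlap may come from the shared Col-0 libraries. The chance value with no effect, 0 genes in 20 simulated draws, does not argue against this, since each draw called at most 1 gene per line. With each line against a different single Col-0 library, a test added after the overlaps had been seen, the overlaps were 1 to 344 at 22 °C and 8 to 16 at 28 °C, with fewer genes called per line.

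The last set asked which genes responded to warmth differently from Col-0. For brl3-2 106 genes had a more positive and 74 a more negative response (85 and 94 on nuclear protein-coding genes, 2796 differed without the 2 doubted libraries). The heat shock list was called down. By itself it was not called with warmth in Col-0 (8 rose and 6 fell of 26, adjusted p = 0.26) or brl3-2 (3 rose and 10 fell of 26, adjusted p = 0.0896). Among heat shock genes 2 of 26 passed downward, MBF1C by -3.74 and HSFA7A (AT3G51910) by -1.40 (median -1.14, 5 over the list alone, adjusted p = 5.44e-08, adjusted p = 0.371 with an estimated correlation, and -0.76 as median with bounds). Among PIF4-pathway genes 1 of 24 passed downward, PRE1 by -1.60 (median -0.62, 4 over the list alone, adjusted p = 0.00514, adjusted p = 0.536 with an estimated correlation), lost without replicate 1 of Col-0 at 22 °C (0.0577). Among osmoprotectant genes 1 of 15 passed downward, GolS1 by -1.53 (median -0.38, 2 over the list alone, adjusted p = 0.034, adjusted p = 0.371 with an estimated correlation), lost without replicate 1 of Col-0 at 22 °C (0.162), replicate 2 of brl3-2 at 22 °C (0.101) or replicate 2 of brl3-2 at 28 °C (0.0672). Photosynthesis was called down, 0 of 22 passed (median -0.22, 0 over the list alone, adjusted p = 0.0302, adjusted p = 0.997 with an estimated correlation), lost without replicate 1 of Col-0 at 22 °C (0.253), replicate 1 of Col-0 at 28 °C (0.151), replicate 1 of brl3-2 at 22 °C (0.377) or replicate 2 of brl3-2 at 28 °C (0.198). Flavonoid genes were called up, 0 of 17 passed (median 1.102, 0 over the list alone, adjusted p = 0.00729, adjusted p = 0.834 with an estimated correlation, and 0.98 as median with bounds), lost without replicate 1 of Col-0 at 22 °C (0.0513) or replicate 2 of brl3-2 at 28 °C (0.0672). Jasmonate genes were called up, 0 of 18 passed (median 0.88, 1 over the list alone, adjusted p = 0.00753, adjusted p = 0.834 with an estimated correlation), lost without replicate 1 of Col-0 at 22 °C (0.17) or replicate 2 of brl3-2 at 28 °C (0.234). Upward were PFA-DSP2 (AT2G32960) (3.12, a smaller fall), PCS1 (AT5G02190) (3.08), CKX4 (AT4G29740) (2.82), EBF2 (2.64) and MYB13 (AT1G06180) (2.58). Downward were also P1R3 (-3.40), PGL1 (AT1G13700) (-2.79), EXLA1 (-2.35) and the xylan gene FRA8 (AT2G28110) (-2.29). None of the 10 kept its call in every leave-one-out. Without replicate 1 or 2 of Col-0 the count was 0 or 87 at 22 °C and 0 or 1 at 28 °C. Without replicate 1 or 2 of brl3-2 it was 0 at 22 °C (3416 had unadjusted p below 0.05 with all libraries), and 22 or 8 at 28 °C. DESeq2 called 992 genes, and the simulated recovery was 6% (2-fold) and 70% (4-fold).

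For pSUC2-BRL3 the same question gave 175 genes more positive and 225 more negative (2997 without the 2 doubted libraries, 3264 without the other pair). The auxin and PIF4-pathway lists were called down. Among auxin response genes 2 of 17 passed downward, IAA6 by -3.06 and IAA19 by -2.21 (median -0.85, 9 over the list alone, adjusted p = 3.13e-07, adjusted p = 0.17 with an estimated correlation). Among PIF4-pathway genes 2 of 24 passed downward, PRE1 by -1.34 (median -0.97, 6 over the list alone, adjusted p = 3.53e-07, adjusted p = 0.154 with an estimated correlation). Among flavonoid genes 1 of 17 passed upward, TT5 by 2.17 (median 1.24, 1 over the list alone, adjusted p = 0.000702, adjusted p = 0.481 with an estimated correlation, and 1.02 as median with bounds). Among heat shock genes 2 of 26 passed downward, MBF1C by -2.39 (median -0.42, 6 over the list alone, adjusted p = 0.0153, adjusted p = 0.543 with an estimated correlation, and -0.21 as median with bounds), lost without replicate 2 of Col-0 at 22 °C (0.15), replicate 2 of pSUC2-BRL3 at 22 °C (0.268) or replicate 2 of pSUC2-BRL3 at 28 °C (0.249). Among salicylic acid genes 1 of 11 passed upward, SARD1 by 4.18 (median 2.103, 4 over the list alone, adjusted p = 0.0062, adjusted p = 0.17 with an estimated correlation), lost without replicate 2 of pSUC2-BRL3 at 28 °C (0.122). Brassinosteroid signalling was called down, 0 of 12 passed (median -0.64, 6 over the list alone, adjusted p = 0.00229, adjusted p = 0.154 with an estimated correlation). Cold-regulated genes were called up, 0 of 14 passed (median 2.64, 0 over the list alone, adjusted p = 0.000868, adjusted p = 0.479 with an estimated correlation), lost without replicate 1 of pSUC2-BRL3 at 28 °C (0.644). Jasmonate genes were called up, 0 of 18 passed (median 0.85, 6 over the list alone, adjusted p = 0.00715, adjusted p = 0.543 with an estimated correlation), lost without replicate 1 of Col-0 at 22 °C (0.126) or replicate 2 of pSUC2-BRL3 at 28 °C (0.249). Photosynthesis was called down, 0 of 22 passed (median -0.28, 0 over the list alone, adjusted p = 0.028, adjusted p = 0.718 with an estimated correlation), lost without replicate 1 of Col-0 at 22 °C (0.219), replicate 1 of Col-0 at 28 °C (0.092), replicate 2 of pSUC2-BRL3 at 22 °C (0.224) or replicate 1 of pSUC2-BRL3 at 28 °C (0.644). Root markers were called up, 0 of 6 passed (median 1.39, 2 over the list alone, adjusted p = 0.0181, adjusted p = 0.436 with an estimated correlation), lost without replicate 1 of Col-0 at 22 °C (0.294), replicate 2 of Col-0 at 22 °C (0.127), replicate 1 of Col-0 at 28 °C (0.052), replicate 2 of Col-0 at 28 °C (0.458), replicate 1 of pSUC2-BRL3 at 22 °C (0.149), replicate 2 of pSUC2-BRL3 at 22 °C (0.278), replicate 1 of pSUC2-BRL3 at 28 °C (0.29) or replicate 2 of pSUC2-BRL3 at 28 °C (0.195).

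Upward in pSUC2-BRL3 were ProT3 (AT2G36590) (4.51), ABCG27 (AT3G52310) (4.38), PAP17 (3.73), LSU2 (3.59) and NRT1.7 (AT1G69870) (3.44). Mean ABCG27 and LSU2 did not rise there. Downward were P1R3 (-5.39), HSP23.5 (-2.71), BZIP61 (AT3G58120) (-2.70) and GASA6 (AT1G74670) (-2.62). NRT1.7 and P1R3 kept their calls in every leave-one-out. The count was 22 without replicate 1 of Col-0 at 22 °C, and 14 or 41 without replicate 1 or 2 of Col-0 at 28 °C. It was 70 or 19 without replicate 1 or 2 of pSUC2-BRL3 at 22 °C, and 133 without its replicate 1 at 28 °C. DESeq2 called 1252 genes, and the simulated recovery was 9% (2-fold) and 60% (4-fold).

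For BRL3ox 254 genes responded more positively and 275 more negatively than in Col-0 (1428 without the 2 doubted libraries). The flavonoid list was called up. Among flavonoid genes 6 of 17 passed upward, PAP1 by 5.93 and DFR by 5.72 (median 3.27, 13 over the list alone, adjusted p = 3.14e-14, adjusted p = 0.378 with an estimated correlation, and 3.23 as median with bounds). Among brassinosteroid biosynthesis genes 2 of 10 passed downward, DWF4 by -1.71 and DWF1 (AT3G19820) by -1.03 (median -0.94, 3 over the list alone, adjusted p = 0.00114, adjusted p = 0.378 with an estimated correlation). Among jasmonate genes 2 of 18 passed upward, AOC2 by 2.203 and AOC1 by 1.77 (median 1.198, 4 over the list alone, adjusted p = 0.000877, adjusted p = 0.491 with an estimated correlation), lost without replicate 1 of BRL3ox at 22 °C (0.177). Among phloem genes 1 of 19 passed upward, the callose synthase gene CalS7 (AT1G06490) by 1.62 (median 0.27, 1 over the list alone, adjusted p = 0.013, adjusted p = 0.378 with an estimated correlation), lost without replicate 1 of BRL3ox at 22 °C (0.202). Photosynthesis was called down, 0 of 22 passed (median -0.74, 9 over the list alone, adjusted p = 5.65e-08, adjusted p = 0.394 with an estimated correlation). Cell cycle genes were called up, 0 of 17 passed (median 0.89, 3 over the list alone, adjusted p = 0.00106, adjusted p = 0.378 with an estimated correlation). Upward were LDOX (ratio of ratios 69.8, 17.9 to 592, 2 counts in Col-0 at 28 °C), GSTF12 (AT5G17220) (5.75), PAP17 (5.23) and LSU2 (3.86). Mean LDOX and DFR fell less than in Col-0. Downward were P1R3 (-4.42), PAR1 (-3.29), Fes1B (-3.25), HAT1 (AT4G17460) (-2.77) and EXLA1 (-2.71). Only P1R3 kept its call in every leave-one-out. The count was 22 or 250 without replicate 1 or 2 of Col-0 at 22 °C, and 4 or 26 at 28 °C. It was 7398 without replicate 1 of BRL3ox at 22 °C, and 73 or 15 without replicate 1 or 2 of BRL3ox at 28 °C. DESeq2 called 1776 genes, and the simulated recovery was 7% (2-fold) and 64% (4-fold).

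Between pSUC2-BRL3 and brl3-2, where the question was whether the 2 lines responded differently, 0 genes had a more positive and 3 a more negative response. They were EBF2 (-2.49), the desaturase gene ADS1 (-2.33) and the ethylene receptor gene ERS2 (AT1G04310) (-2.26). Without the 2 doubted libraries 262 genes differed, without the other pair 1236, and DESeq2 called 302. Unadjusted p was below 0.05 for 2253 genes. All lists called here had no member past the threshold. Auxin response was called down, 0 of 17 passed (median -0.70, 2 over the list alone, adjusted p = 1.46e-06, adjusted p = 0.431 with an estimated correlation). The PIF4 pathway was called down, 0 of 24 passed (median -0.37, 1 over the list alone, adjusted p = 0.0178, adjusted p = 0.614 with an estimated correlation), lost without replicate 2 of brl3-2 at 22 °C (0.0538), replicate 2 of pSUC2-BRL3 at 22 °C (0.171) or replicate 2 of pSUC2-BRL3 at 28 °C (0.0935). Brassinosteroid signalling was called down, 0 of 12 passed (median -0.26, 1 over the list alone, adjusted p = 0.0479, adjusted p = 0.431 with an estimated correlation), lost without replicate 1 of brl3-2 at 22 °C (0.0749), replicate 2 of brl3-2 at 22 °C (0.0538), replicate 1 of brl3-2 at 28 °C (0.0824), replicate 2 of brl3-2 at 28 °C (0.0598), replicate 2 of pSUC2-BRL3 at 22 °C (0.171), replicate 1 of pSUC2-BRL3 at 28 °C (0.0602) or replicate 2 of pSUC2-BRL3 at 28 °C (0.134). Heat shock genes were called up, 0 of 26 passed (median 0.56, 0 over the list alone, adjusted p = 0.00397, adjusted p = 0.635 with an estimated correlation), lost without replicate 1 of pSUC2-BRL3 at 22 °C (0.0886) or replicate 1 of pSUC2-BRL3 at 28 °C (0.0699). Cold-regulated genes were called up, 0 of 14 passed (median 2.62, 0 over the list alone, adjusted p = 2.38e-06, adjusted p = 0.431 with an estimated correlation), lost without replicate 1 of pSUC2-BRL3 at 28 °C (0.215). Root markers were called up, 0 of 6 passed (median 1.71, 0 over the list alone, adjusted p = 0.0129, adjusted p = 0.431 with an estimated correlation), lost without replicate 2 of brl3-2 at 28 °C (0.131), replicate 2 of pSUC2-BRL3 at 22 °C (0.0607), replicate 1 of pSUC2-BRL3 at 28 °C (0.0602) or replicate 2 of pSUC2-BRL3 at 28 °C (0.0875). None of the 3 genes kept its call in every leave-one-out. The count was 0 without either library of either line at 22 °C, 0 or 1 without replicate 1 or 2 of brl3-2 at 28 °C, and 0 or 23 without replicate 1 or 2 of pSUC2-BRL3 at 28 °C. The simulated recovery was 6% (2-fold) and 59% (4-fold).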

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

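All tests weighed in this part, their thresholds and the clock marker genes were chosen only after the results were seen, and 4 tests replaced earlier forms whose output had been seen. A difference between groups, tested as an interaction, flagged the results that follow, and all are log2 differences from the Col-0 response unless stated.

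For brl3-2 180 genes differed. List medians were -0.62 for the PIF4 pathway, -1.14 for heat shock (-0.76 with bounds for 0 counts), -0.22 for photosynthesis, 1.102 for flavonoids (0.98), 0.88 for jasmonate and -0.38 for osmoprotectants. Genes were PFA-DSP2 3.12, PCS1 3.08, CKX4 2.82, EBF2 2.64, MYB13 2.58, MBF1C -3.74, P1R3 -3.40, PGL1 -2.79, EXLA1 -2.35 and FRA8 -2.29. For pSUC2-BRL3 400 genes differed. List medians were -0.64 for brassinosteroid signalling, -0.97 for the PIF4 pathway, -0.85 for auxin, -0.42 for heat shock (-0.21 with bounds), 2.64 for cold, -0.28 for photosynthesis, 1.39 for root, 1.24 for flavonoids (1.02), 2.103 for salicylic acid and 0.85 for jasmonate. Genes were ProT3 4.51, ABCG27 4.38, PAP17 3.73, LSU2 3.59, NRT1.7 3.44, P1R3 -5.39, IAA6 -3.06, HSP23.5 -2.71, BZIP61 -2.70 and GASA6 -2.62. For BRL3ox 529 genes differed. List medians were -0.94 for brassinosteroid biosynthesis, 0.27 for phloem, -0.74 for photosynthesis, 0.89 for cell cycle, 3.27 for flavonoids (3.23 with bounds) and 1.198 for jasmonate. Genes were LDOX 5.93 (from 2 counts in Col-0 at 28 °C, a ratio of ratios of 69.8, counting interval 17.9 to 592), GSTF12 5.75, DFR 5.72, PAP17 5.23, LSU2 3.86, P1R3 -4.42, PAR1 -3.29, Fes1B -3.25, HAT1 -2.77 and EXLA1 -2.71. Between pSUC2-BRL3 and brl3-2 3 genes differed, EBF2 -2.49, ADS1 -2.33 and ERS2 -2.26. List medians there were -0.26 for brassinosteroid signalling, -0.37 for the PIF4 pathway, -0.70 for auxin, 0.56 for heat shock, 2.62 for cold and 1.71 for root. In data no comparison used, the line without a gene name reached 36.4 CPM in BRL3ox at 28 °C against 26.7 CPM in Col-0.

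The heat shock list was called down at 28 °C in all 3 lines against Col-0, but in none with an estimated correlation (adjusted p = 0.0584 in brl3-2, 0.0552 in pSUC2-BRL3 and 0.187 in BRL3ox). A single odd Col-0 library does not explain it, since the smaller median log2 ratio of 1 Col-0 library to the lines was 0.717. Clock phase at harvest could not be told apart as a cause: the lines' lowest phase index lay 0.535 above the highest of Col-0, but within pSUC2-BRL3 the later library was 0.54 higher in these genes. An effect following BRL3 level in 1 direction was not excluded for the list. Of its 26 members 10, HSP101 and MBF1C among them, were lower by more than 2 SE in both brl3-2 and BRL3ox. This held whichever Col-0 library each line was set against. Being lower in both goes against such an effect for these 10, but they were picked by that same outcome. The other 16 could not be told apart, as their medians plus 2 SE reached 0.464. Earlier forms of this test used the 5 members called in both lines, the list medians, -1.27 (SE 0.23) in brl3-2 and -0.62 (SE 0.35) in BRL3ox, and the 1 member still called in both against different Col-0 libraries.

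The BRL3ox libraries at 22 °C differed from each other. Clock phase at harvest stays open: the index differed by 3.15, but by 3.02 in pSUC2-BRL3 at 28 °C. There 1576 genes lay 2-fold apart, against 4523. The index markers were chosen after these libraries were seen to differ. The share of green tissue stays open too, as no profile of it was measured. The photosynthesis median difference of 0.446 lay inside the 0.0694 to 0.524 of the other pairs. Replicate 2 alone does not make the calls against Col-0, since 2506 of 6197 remained without it.

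HB17 was higher in BRL3ox at both temperatures, at 692 ± 17.5 and 662 ± 9.55 CPM. Extra copies of a stretch that raise its genes alike are excluded, as the 10 nearest genes reached at most 2.1005 (log2 difference plus 2 SE) against at least 5.40 (minus 2 SE) for HB17. An activation spreading unequally stays open: 4 of the 10, consecutive on 1 side from MPK17 (0.84), were higher at 22 °C and 0 at 28 °C. Of the 4, 2 were higher at 22 °C in brl3-2 or pSUC2-BRL3 too. BRL3 level stays open: warmth raised BRL3 in BRL3ox but not HB17 (-0.0645), which fell in Col-0 (-1.25). An insertion acting on HB17 alone was not tested.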

How the results depend on the processing

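The fits without the 2 doubted libraries or the other pair, on nuclear protein-coding genes, with split Col-0 libraries, and of lists without each library were chosen after the results were seen. Counts of changed genes follow the order brl3-2, pSUC2-BRL3 and BRL3ox against Col-0, then pSUC2-BRL3 against brl3-2, at 22 °C, at 28 °C and for temperature responses. The cause was not tested, but only the shared fit links the doubted libraries to comparisons without them.

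DESeq2 moved 10 counts over 1.5 times: 1277 and 953 (first and last at 22 °C), 1458, 673, 1168 and 1055 at 28 °C, and 992, 1252, 1776 and 302 for responses. Without both doubted libraries the counts were 3433, 6594, 3516 and 3715 at 22 °C, 2958, 720, 3488 and 1432 at 28 °C, and 2796, 2997, 1428 and 262 for responses. Without the other pair they were 3413, 6567, 3532 and 3724, then 2947, 2145, 3481 and 2661, and then 2779, 3264, 1447 and 1236. Dropping the filter gave 146 for pSUC2-BRL3 against brl3-2 at 22 °C and 19 for its response. Correlations of replicate differences between groups ran from 0.0512 to 0.267 at 28 °C, 5 of 6 above 0.1, from -0.153 to 0.0715 at 22 °C and from -0.294 to 0.205 across temperatures, so a shared replicate pattern at 28 °C is not excluded. A replicate block gave 168 and 1 (first and last at 22 °C), 112 for pSUC2-BRL3 at 28 °C and 60, 212 and 311 for responses against Col-0. On nuclear protein-coding genes the balance of higher and lower calls turned in 4 comparisons, the share of higher calls going from 52.6% to 49.7% for temperature in brl3-2, from 50.2% to 47.2% in pSUC2-BRL3, from 47.6% to 55.5% for pSUC2-BRL3 against Col-0 at 22 °C and from 58.9% to 47.5% for the brl3-2 response. It moved from 51.5% to 59.1% for BRL3ox against Col-0 at 22 °C and from 48.0% to 36.1% for its response.

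Leaving out 1 library gave 6054 to 6797 for temperature in Col-0, 4699 to 6913 in pSUC2-BRL3 and 4728 to 9381 in BRL3ox. At 22 °C the ranges were 0 to 86, 71 to 914, 853 to 10577 and 1 to 2. At 28 °C they were 43 to 358, 14 to 294, 29 to 57 and 1 to 211, and for responses 0 to 87, 14 to 378, 4 to 7398 and 0 to 23. Leaving out a library kept 401 of 768 calls of named genes and reversed 0. Of 159 named calls DESeq2 kept 159, its size factors 158, no filter 159, the block 134, the other pair 159, and the fits without both libraries and on nuclear genes 157 each.

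Of 112 list calls 0 held with an estimated correlation, and 63 held in every leave-one-out. Without both doubted libraries 92 held, 20 were lost and 26 were gained, and without the other pair 89, 23 and 23. The size factors kept 111 list calls, no filter 103 and the block 111, and the rotation test fry kept 57. Of the lost, 2 reversed without both doubted libraries: abscisic acid in pSUC2-BRL3 against Col-0 at 28 °C (adjusted p = 0.325, leave-one-out 1.53e-09 to 0.231) and cold-regulated in pSUC2-BRL3 against brl3-2 at 28 °C (adjusted p = 0.181, leave-one-out 1.63e-18 to 0.144). Without the other pair photosynthesis in pSUC2-BRL3 against brl3-2 at 28 °C reversed (adjusted p = 0.900). Similarity of the temperature response to Col-0 without the filter was r = 0.566, 0.498 and 0.504 in brl3-2, pSUC2-BRL3 and BRL3ox, and 0.634 for pSUC2-BRL3 without both libraries. Leave-one-out ranges were 0.731 to 0.790, 0.625 to 0.715 and 0.443 to 0.724. Overlaps of line effects, in the order of the report, were 120 and 117 for the first 2 with the block, and 2276, 1316, 2723, 355, 916 and 433 without both libraries. They were 2267, 1311, 2727, 756, 910 and 1438 without the other pair, and with split Col-0 libraries 32, 44, 344, 8, 13 and 16 or 1, 1, 81, 11, 12 and 12. Leave-one-out ranges were 0 to 107, 0 to 1626, 69 to 4706, 6 to 113, 13 to 51 and 10 to 188. Simulated 2-fold interactions were mostly missed (6% recovered for brl3-2).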

Other observations

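The library values here were picked after the results were seen. Clock gene RNA differed between libraries. LHY was at 811 and 677 CPM in Col-0 at 22 °C, 406 and 126 in BRL3ox, and PRR5 at 0.363 and 10.7 in BRL3ox at 22 °C and 43.7 and 12.5 in pSUC2-BRL3 at 28 °C. Plastid-encoded genes held 1.63% to 4.66% of counts at 22 °C.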
